A study of Mus musculus with 6 samples.

How the data were processed

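RNA was measured by poly(A)-selected RNA-seq in 6 libraries of mouse cerebral cortex at embryonic day 14.5 (E14.5), 3 from control embryos and 3 from embryos labelled Brg1 cKO (conditional knockout). Brg1 is the older name of Smarca4, an ATPase of the BAF (SWI/SNF) chromatin-remodelling complex. Per the labels' protocols, the dissected cortex was extracted with Trizol, 1 μg of total RNA went into each library, and cDNA fragments of 370 to 420 bp were selected. The labels give the cell type as neural progenitor, but the protocol names whole dissected cortex, so the values are treated as tissue values. Replicates are titled as biological, and the labels do not say whether they came from separate litters, so p-values measure the spread between these libraries.

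Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3 on build mm10. The authors deposited FPKM values (fragments per kilobase of gene length, scaled to library size) for 54532 genes, with 1 column per library, next to each gene's length and position. The annotation release, the strand setting and the scaling method are not given in the sources used here. Of the gene identifiers, 99.9% were found in GENCODE M21, 98.3% had the same start and end there, and 98.0% had a deposited length equal to the union of the annotated exons. Because the strand setting is not stated, reads from a gene and an overlapping antisense gene cannot be told apart, and such partners are named beside the genes concerned.

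Reads per gene were worked out from the deposited FPKM. FPKM times gene length was a whole multiple of 1 step per library within a tolerance of 0.01 for 100% of values, which gave 17727069, 17199032 and 18106834 reads for control replicates 1 to 3 and 17249724, 16900332 and 18689748 for cKO replicates 1 to 3. The same step showed that the deposited values carry a scaling factor per library, of 0.965, 0.958 and 0.904 in the controls and 1.07, 1.07 and 1.09 in the cKO. Median-ratio factors computed from the deposited FPKM were 1.01 in every library, so the deposited values were already on a common median-ratio scale. At this depth 3 reads, the floor used for a gene with no read in a group, correspond to between 1.61e-05% and 1.78e-05% of a library's reads. Such floors and read intervals cover counting error only.

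The main test was limma 3.58.1 in R 4.3.3, on log2(FPKM + 0.5) of genes with a mean FPKM of at least 0.5 over the 6 libraries, with empirical Bayes moderation and a mean-variance trend. It was two-sided, had no block, and used a Benjamini-Hochberg adjusted p under 0.05 as the threshold over 15915 genes. A log2 fold change is on the log2(FPKM + 0.5) scale and understates the change of low genes, while a fold is a ratio of mean FPKM. Values are means with the SD between the 3 libraries of a group, and SE is the moderated standard error of a log2 fold change. For single values, 3 libraries against 3 cannot go below p = 0.1 in an exact permutation test.

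Before the data were examined, 39 gene lists with 971 distinct genes were fixed. They covered cell types of the embryonic cortex and its surroundings, pathways, BAF subunits, genes of 4 classes of cortical malformation and checks of RNA quality, and 1 gene was not found in the table. Lists with at least 5 tested genes (36 lists) were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it, and adjusted over the 36 lists. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. Transcription factors were taken from the family column of the deposited table.

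Genes are named by a rule that was also fixed beforehand. It takes Smarca4, the 10 protein-coding genes with the largest increase and the 10 with the largest decrease among those past the threshold, with no overlap between groups and a mean of at least 1 FPKM in the higher group, leaving out Xist, Tsix and chromosome Y. It adds up to 4 members of each list past the threshold, and Smarca2, Arid1a, Pax6, Sox2, Hes5, Eomes, Neurog2, Tbr1, Bcl11b, Reln, Cdkn1a, Mki67, Dcx, Lama1 and Cdh2 whatever their result. The rule gave 78 genes, of which some are not reported here.

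Whether replicate numbers pair the libraries was checked by correlating, across genes, the deviations of same-numbered libraries from their group means. The correlations were 0.23, 0.30 and 0.53 for numbers 1 to 3, all above the minimum of 0.1 set for pairing, so a fit with the replicate number as a block is given wherever it changes a call or moves a count by more than 1.5 times. The pairing comes from the values, since the labels give the numbers no meaning. Control replicates 1 and 2 each correlated slightly better with the other number (0.28 and 0.31). Deviations from a group mean cancel within the group, so the deviation shared by the replicate 3 libraries tends to make these correlations positive. The check therefore does not support the pairing of numbers 1 and 2, and the block rests mainly on replicate 3.

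The gene fit without a block, and camera at the preset correlation, were tested on simulated data built from these libraries. The other fits and tests were not assessed in this way. Genes were simulated independently of each other, so the preset correlation itself was not tested, nor was a deviation shared by same-numbered libraries. Among 15890 genes of a simulated cKO against control comparison, 13.5% of genes changed 2-fold and 63.0% of those changed 4-fold were called, all in the right direction, with 2 false calls. A simulation with no gene changed gave 3 calls.

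Alternatives fixed beforehand changed the pseudocount, the filter, the scaling, the moderation, the sample weights, the block, the gene set test and the gene classes, and left out each library in turn. Added after seeing the data were leaving out both replicate 3 libraries, voom on the worked-out reads with and without the block, values without the scaling factor, a term for sex, autosomes only, and a loess correction for GC content and length with and without the block. In sex-linked genes, control replicates 1 and 2 were the only libraries with a female pattern. With a term for sex, the group difference was therefore that of the cKO libraries from control replicate 3 alone. That fit could not separate sex from the deviation of this library. Without both replicate 3 libraries, both controls had the female and both cKO libraries the male pattern, so group and sex coincided. Figures were drawn with matplotlib 3.10.9.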

Results

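The series compared the E14.5 cerebral cortex of mice lacking Brg1 in the cortex with that of control mice, and its title places the comparison in the context of malformations of cortical development. Each group had 3 libraries of between 16900332 and 18689748 reads, in which 23197 to 25116 genes had at least 1 read. The replicate 3 libraries of both groups stood apart from replicates 1 and 2. Component 1 held 40.5% and component 2 held 34.1% of the variance, and mitochondrial genes took 1.08% and 0.988% of the reads in the replicate 3 libraries against 2.01% to 2.37% in the other 4. The groups also differed in sex. Xist, the RNA of the inactive X chromosome, stood at 145 and 153 FPKM in control replicates 1 and 2 and at 0.0102 FPKM in control replicate 3, while the highest value in the cKO was 0.0151 FPKM. The Y-linked Ddx3y was at 0 FPKM in control replicates 1 and 2, at 9.21 FPKM in control replicate 3 and between 7.53 and 13.2 FPKM in the cKO.

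**Figure D1:**
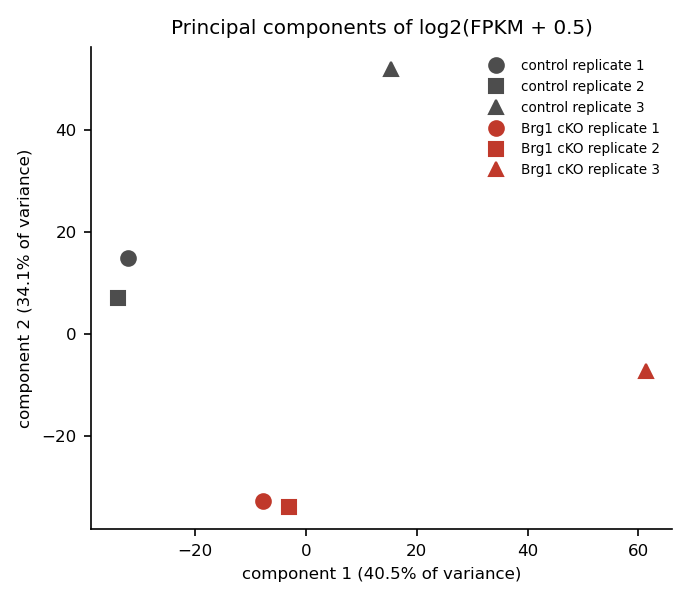
Principal components of log2(FPKM + 0.5) over the 15915 genes tested, with 1 point per library, colour for the group and shape for the replicate number. The axes give each component's share of variance, 40.5% and 34.1%, and the replicate 3 libraries lie away from replicates 1 and 2 of their group.

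The targeted gene was lower in every library labelled cKO than in every control. Smarca4 (ENSMUSG00000032187, mm10 chromosome 9, 21616169 to 21704230, plus strand) measured 57.2, 97.8 and 67.9 FPKM in the controls and 37.4, 24.98 and 34.8 FPKM in the cKO. The cKO mean was 43.6% of the control mean (32.4 ± 6.57 against 74.3 ± 21.1 FPKM, SD, n = 3 each). The log2 fold change of -1.17 (SE 0.25) did not pass the threshold in limma (adjusted p = 0.068, and 0.069 with the replicate block), and it passed in 4 of 25 alternatives, over which the adjusted p ran from 0.0036 to 0.21. A gene-level value counts reads over all annotated exons, including exons outside the deleted part. In whole dissected tissue it also counts RNA of any cells in which the gene was not deleted. The deposited column names of the cKO libraries name Emx1 beside Brg1, and the share of cells with the deletion was not measured.

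Loss of Brg1 was accompanied by lower expression of several projection neuron genes and higher expression of several genes of the cortical hem and of the diencephalon. The adhesion molecule Cntn2 (TAG-1) of migrating neurons and growing axons fell 8.01-fold, and the neuronal bHLH factor Neurod6 fell 3.55-fold. The hem ligand Wnt2b rose 6.13-fold and the secreted Wnt inhibitor Wif1 rose 8.91-fold. Of 15915 genes tested, 344 changed, 134 of them higher and 210 lower in the cKO, and 282 changed at least 2-fold. The control and cKO values of all 344 were apart, and so were those of 4175 of the genes tested (26.2%, where chance gives 10%). With the replicate block, 886 genes changed (370 higher and 516 lower), 445 of them at least 2-fold, and these held 342 of the 344. The direction of the majority depended on the scaling, since 39.0% of calls were higher in the deposited FPKM, 61.9% after rescaling to a common sum and 64.0% without the scaling factor. These 2 scalings moved the median log2 fold change of all genes from -0.07 to 0.07 and 0.10. The majority also turned with the replicate block and voom (962 higher and 903 lower), where that median stayed at -0.08.

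**Figure D2:**
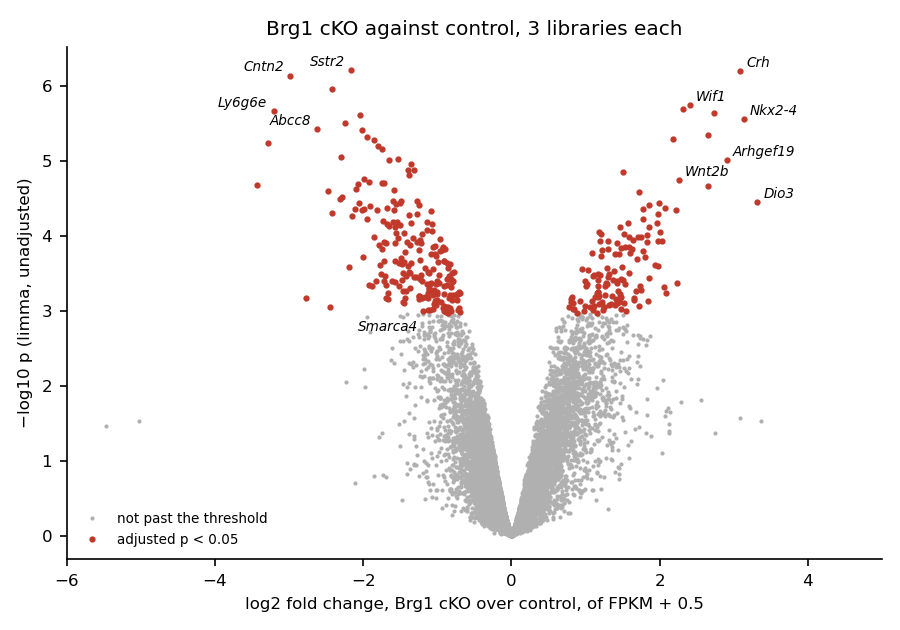
Log2 fold change of FPKM + 0.5, cKO over control, against the unadjusted limma p on a negative log10 scale, for 15915 genes. The 344 genes past the threshold are in red, 134 on the right and 210 on the left, and Smarca4 did not pass.

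Among the 10 largest increases, the type 3 deiodinase Dio3, which inactivates thyroid hormone, rose from 0.697 ± 0.405 to 11.3 ± 4.33 FPKM (log2 fold change 3.31, SE 0.36, adjusted p = 0.0116; chromosome 12, 110279068 to 110281097). The hypothalamic homeobox gene Nkx2-4 had no read in any control and 3.98 ± 1.14 FPKM in the cKO, at least 38.1-fold higher against a floor of 3 reads per library (adjusted p = 0.0045; chromosome 2, 147083316 to 147085445). Crh, which encodes corticotropin-releasing hormone, and the bHLH factor Olig3 had 3 reads each over the controls. The ratios of scaled reads were 91.4 for Crh (95% exact binomial interval 31.0 to 445.5) and 98.4 for Olig3 (33.4 to 479.5). The others were the guanine nucleotide exchange factor Arhgef19 (14.7-fold), the glutathione transferase Gsta4 (7.21-fold), the homeobox gene Uncx (22.6-fold), Mro (7.3-fold), Wif1 and Wnt2b, with adjusted p between 0.0044 and 0.0095.

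Among the 10 largest decreases, Cntn2 (chromosome 1, 132509427 to 132543256) fell from 140 ± 13.1 to 17.5 ± 3.63 FPKM (log2 fold change -2.98, SE 0.18, adjusted p = 0.0039). The neighbouring genes Abcc8 and Kcnj11 on chromosome 7, which encode the 2 subunits of an ATP-sensitive potassium channel, fell 10.1-fold and 6.13-fold. Ly6g6e fell 70.7-fold, the melanin synthesis enzyme Dct 17.02-fold, the melanocortin receptor Mc4r 6.59-fold, Vxn 5.25-fold, the Rac exchange factor Tiam2 5.62-fold and the transcription factor Nfix 5.13-fold, with adjusted p between 0.0044 and 0.0443. The fold of Ly6g6e is uncertain, since its cKO level was only 0.0687 ± 0.0231 FPKM, against 4.86 ± 1.22 FPKM in the control. Its log2 fold change ran from -5.78 to -2.43 over 25 alternatives. Tiam2 overlaps Tfb1m, and Nfix overlaps Lyl1, on the opposite strand.

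**Figure D3:**
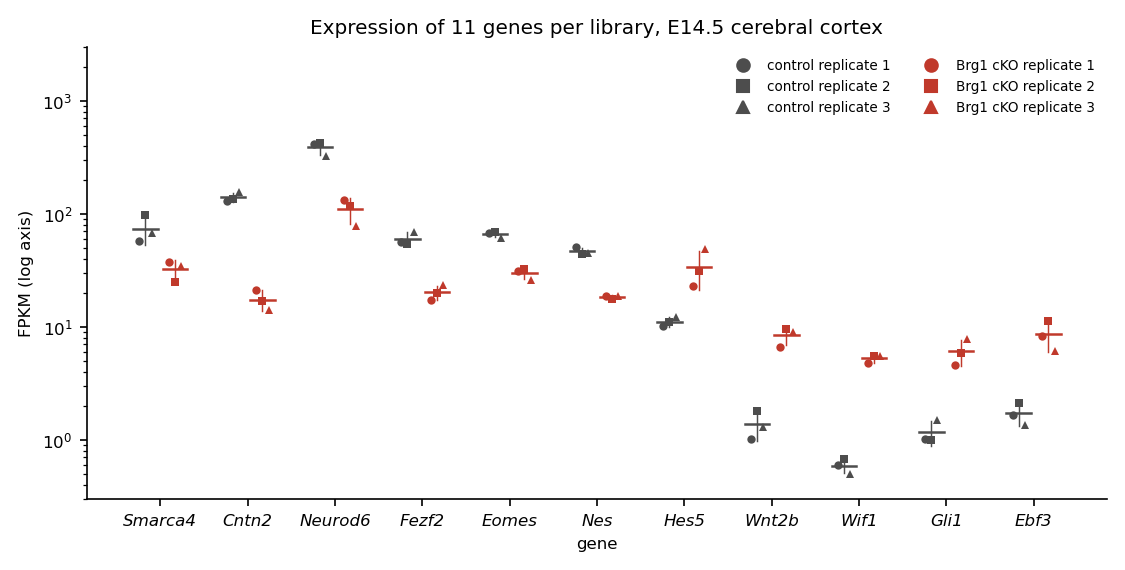
FPKM on a log axis for 11 genes in each of the 6 libraries, with shape for the replicate number, horizontal lines for group means and vertical lines for the SD (n = 3). All 11 genes are apart between groups, from Smarca4 at 74.3 against 32.4 FPKM to Ebf3 at 1.72 against 8.58 FPKM.

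In the list of intermediate progenitors, the basal progenitors that give rise to projection neurons, 6 of 19 tested genes fell and none rose, and 12 fell and 1 rose when adjusted over the list alone. The median log2 fold change was -1.11 (camera adjusted p = 7.8e-08, and adjusted p = 0.11 with an estimated correlation). Eomes, their defining T-box factor, fell from 66.3 ± 4.09 to 29.9 ± 3.43 FPKM (adjusted p = 0.0155), with the antisense gene Gm33460 overlapping its exons. The somatostatin receptor Sstr2 fell 4.67-fold, Rhbdl3 4.47-fold, Neurod4 4.64-fold and Kif26b 3.12-fold. With the replicate block 10 genes of this list fell, and with a term for sex its median was -0.71. Neurog2, the proneural factor upstream of this lineage, measured 79.3 ± 9.02 FPKM in the cKO against 107 ± 5.17 FPKM and did not pass (adjusted p = 0.18).

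All 19 tested genes of newborn migrating neurons had a negative log2 fold change, with a median of -0.91, and 6 of them fell (13 when adjusted over the list alone; camera adjusted p = 1.2e-11, and adjusted p = 0.11 with an estimated correlation). Neurod6 fell from 389 ± 55.3 to 110 ± 27.9 FPKM, Neurod2 fell 2.84-fold, and the netrin receptor Unc5d fell 2.84-fold. Dcx, the microtubule-associated protein doublecortin, was at 101 ± 43.7 FPKM against 163 ± 24.4 FPKM and did not pass (adjusted p = 0.33). Of 19 tested deep-layer neuron genes, 8 fell and none rose (12 fell and 3 rose when adjusted over the list alone), with a median of -0.88 (camera adjusted p = 1.2e-07, and adjusted p = 0.14 with an estimated correlation). Fezf2, which specifies corticospinal neurons, fell 2.98-fold, Sox5 from 28.5 to 7.13 FPKM, Hs3st4 4.33-fold, Nfib 2.70-fold and Bcl11b (Ctip2) 1.84-fold. Hs3st4 overlaps Gm27040 on the opposite strand. With the block 12 genes of this list fell and 1 rose. Tbr1, a factor of layer 6 neurons, measured 65.8 ± 18.0 against 92.3 ± 5.89 FPKM and did not pass (adjusted p = 0.31).

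Of 16 upper-layer neuron genes, 3 fell, Inhba (9.93-fold) and Dok5 (3.49-fold) among them, and none rose (6 fell and 1 rose when adjusted over the list alone; median -0.46, camera adjusted p = 0.0011, and adjusted p = 0.28 with an estimated correlation), and 6 fell with the replicate block. The median of this list was -0.19 without both replicate 3 libraries (adjusted p = 0.048) and -0.72 with a term for sex (adjusted p = 0.0014). Among 38 genes of the synapse and neuronal excitability, the vesicular glutamate transporter Slc17a7 fell 3.32-fold, Rbfox1 2.80-fold and Rbfox3 (NeuN) 2.54-fold, with 4 falling when adjusted over the list alone. This list passed in the main test (median -0.29, camera adjusted p = 0.033) but not with an estimated correlation (adjusted p = 0.67), with the block (adjusted p = 0.055) or without both replicate 3 libraries (median -0.0037, adjusted p = 0.57, within a range of 2.8e-04 to 0.83 over 27 alternatives, of which it passed in 16), and its median was -0.54 with a term for sex. In the axon guidance and adhesion list, the midline repellent Slit2 (3.45-fold) and the receptor Robo3 (8.62-fold) rose and 4 of 42 genes fell, Cntn2 and Unc5d among them (7 rose and 12 fell when adjusted over the list alone). The list as a whole did not pass (camera adjusted p = 0.094), and with the block 6 of its genes rose and 11 fell.

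Apical radial glia, the stem cells that line the ventricle, showed changes of single genes in both directions. Of 30 tested genes, the Notch effector Hes5 (34.3 ± 13.2 against 11.1 ± 1.08 FPKM, adjusted p = 0.041) and the lipid-binding protein Fabp7 (488 ± 27.0 against 274 ± 24.7 FPKM, adjusted p = 0.046) rose. The intermediate filament Nes (18.5 ± 0.547 against 46.9 ± 3.35 FPKM, adjusted p = 0.0078) and the glycolytic enzyme Aldoc (8.56 ± 3.15 against 42.2 ± 2.13 FPKM, adjusted p = 0.011) fell. Adjusted over the list alone, 6 rose and 8 fell, and the list did not pass (median -0.10, camera adjusted p = 0.51); with the block 3 rose and 7 fell. Pax6 measured 9.07 ± 1.21 against 8.93 ± 1.97 FPKM (adjusted p = 0.95) and Sox2 86.9 ± 17.6 against 57.8 ± 8.39 FPKM (adjusted p = 0.19). In the Notch pathway, Hes5 rose and the glycosyltransferase Mfng fell 2.61-fold among 23 genes (4 rose and 2 fell when adjusted over the list alone). The Notch list passed as higher (median 0.05, camera adjusted p = 0.042, and adjusted p = 0.36 with an estimated correlation), and with the block 3 of its genes rose and 2 fell. It passed in 15 of 27 alternatives, not without both replicate 3 libraries (adjusted p = 0.12), and had a median of 0.24 with a term for sex. In the oligodendrocyte and astrocyte list, Nfix and Sox8 (3.47-fold, overlapping 2810468N07Rik) fell among 15 tested genes, while 12 had a positive log2 fold change. Adjusted over the list alone 2 rose and 3 fell, and the list did not pass (camera adjusted p = 0.093) but passed as higher with the block (adjusted p = 0.030, and adjusted p = 0.51 with the block and an estimated correlation) and without both replicate 3 libraries (adjusted p = 0.010). With the block 1 of its genes rose and 2 fell.

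No gene of G2 and M phase (54 tested) or of S phase (43 tested) passed, over all genes or adjusted over the list alone (limma; with the block 2 genes of G2 and M phase fell). The G2 and M phase list passed as lower (median -0.32, camera adjusted p = 0.0015, and adjusted p = 0.64 with an estimated correlation), and S phase did not (median -0.18, adjusted p = 0.055) but passed with the block (adjusted p = 0.022, and adjusted p = 0.78 with the block and an estimated correlation) and without both replicate 3 libraries (median -0.29, adjusted p = 1.9e-05). The call of the G2 and M phase list was lost without control replicate 1 (adjusted p = 0.15) and without cKO replicate 3 (adjusted p = 0.10). With a term for sex, which compares the cKO libraries with control replicate 3 alone, both lists had positive medians of 0.23 and 0.23. That library had the lowest means of both lists among the controls (3.56 for G2 and M phase and 2.76 for S phase, log2). Over the alternatives, the adjusted p of the list tests ran from 1.7e-11 to 0.64 and from 1.0e-06 to 0.92. Mki67 measured 22.1 ± 11.8 against 32.1 ± 14.3 FPKM and did not pass (adjusted p = 0.67), although it did with the block (adjusted p = 0.0498). Its replicate 3 libraries stood at 15.6 FPKM in the control and 8.50 FPKM in the cKO, and the other 4 libraries between 27.7 and 40.4 FPKM. Among 32 genes of the p53 response and apoptosis none passed over all genes, 2 rose when adjusted over the list alone, and 2 rose and 1 fell with the block (median 0.18, camera adjusted p = 0.036, and adjusted p = 0.24 with an estimated correlation). The list passed in 19 of 27 alternatives, not without both replicate 3 libraries (median 0.052, adjusted p = 0.18), and had a median of 0.082 with a term for sex. Its member Cdkn1a measured 5.20 ± 1.84 against 2.93 ± 0.198 FPKM (adjusted p = 0.20).

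In the list of the cortical hem and choroid plexus, at the medial edge of the cortex, 9 of 25 tested genes rose and none fell (19 rose and 1 fell when adjusted over the list alone), with a median of 1.52 (camera adjusted p = 3.6e-16, and adjusted p = 0.17 with an estimated correlation). Besides Wnt2b, the LIM homeobox factor Lmx1a rose 5.48-fold, the head organiser gene Otx2 4.12-fold and Gmnc, a regulator of multiciliated cells, 5.70-fold. Genes of this list that did not pass included the choroid plexus genes Ttr (4.98-fold higher, adjusted p = 0.28) and Folr1 (10.1-fold higher, adjusted p = 0.17). Both were without overlap between the groups but varied within them, and were named after their values were seen. In the diencephalon and hypothalamus list, 4 of 9 tested genes (24 were listed) rose (8 when adjusted over the list alone), with a median of 1.69, and 1.69 with Nkx2-4 at its bound (camera adjusted p = 1.2e-11, and adjusted p = 0.14 with an estimated correlation). Besides Nkx2-4 and Olig3, the homeobox gene Irx5 rose from 0.0447 ± 0.0219 to 1.82 ± 0.513 FPKM and Irx3 rose 6.15-fold. Of the 9 tested genes 1 stood at 1 FPKM or more in every control, so most reached the expression filter through their cKO values.

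Of 39 Wnt pathway genes 5 rose and none fell (13 rose and 1 fell when adjusted over the list alone; median 0.47, camera adjusted p = 4.7e-08, and adjusted p = 0.28 with an estimated correlation). They included Wnt2b, Wnt8b (3.20-fold) and Wnt3a (3.29-fold), which are ligands of the hem, and the inhibitor Wif1. These ligands also count in the hem and choroid plexus list, so the calls of the Wnt pathway and hem lists are not independent. With the block 7 Wnt pathway genes rose and 1 fell, and without both replicate 3 libraries the median was 0.30. Of 11 Hedgehog pathway genes, 3 rose, among them Gli1 (5.19-fold) and Ptch1 (2.52-fold), which are transcriptional targets of the pathway, and none fell (4 rose and 1 fell when adjusted over the list alone; median 0.27, camera adjusted p = 0.0046, and adjusted p = 0.28 with an estimated correlation). With the block 3 Hedgehog pathway genes rose and 1 fell, and with a term for sex the median was 0.45. Of 15 genes of Cajal-Retzius cells, the early neurons of the cortical surface, Ebf3 (4.98-fold) and Calb2 (2.70-fold) rose (6 rose and 1 fell when adjusted over the list alone; median 0.33, camera adjusted p = 0.0060, and adjusted p = 0.17 with an estimated correlation). With the block 3 genes of this list rose and 1 fell. Their secreted signal Reln measured 16.5 ± 2.83 against 20.6 ± 2.22 FPKM and did not pass (adjusted p = 0.41).

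**Figure D4:**
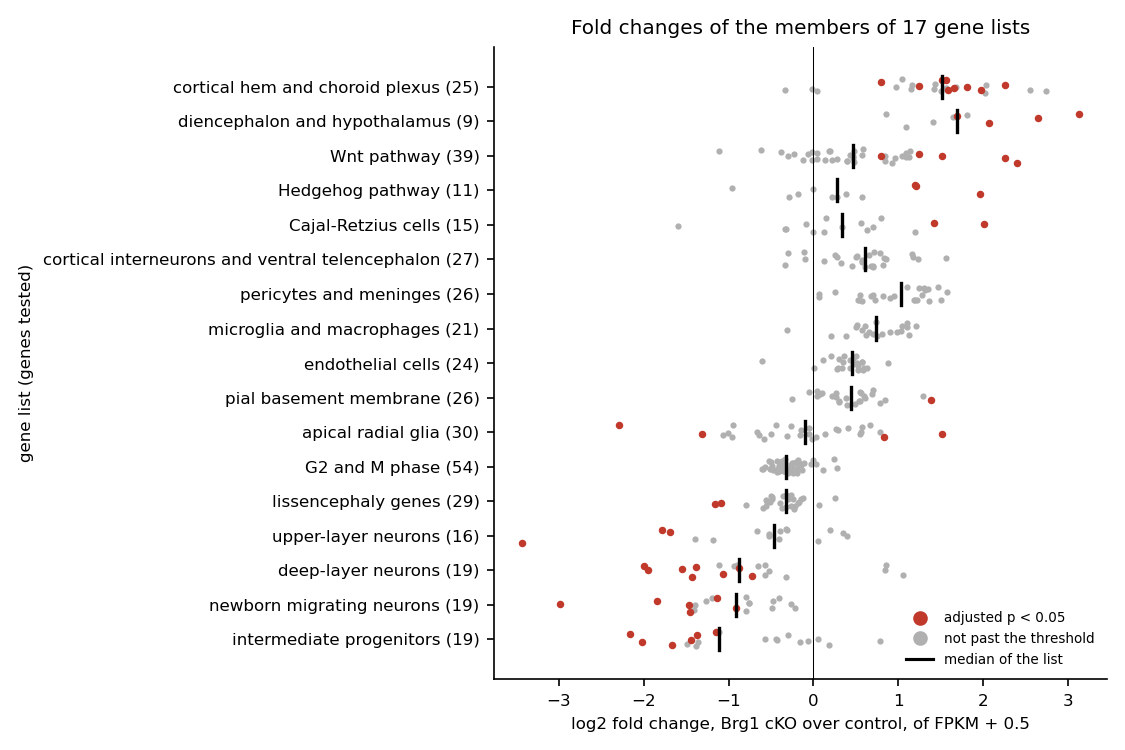
Log2 fold changes of FPKM + 0.5, cKO over control, of the tested members of 17 gene lists, 1 point per gene, in red where it passed the threshold. Black bars mark list medians, from -1.11 in intermediate progenitors to 1.69 in the diencephalon and hypothalamus list.

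The marker lists of pericytes and meninges, microglia and macrophages, endothelial cells, interneurons and erythroid cells passed as higher in the cKO, while no gene of these lists passed over all genes. For pericytes and meninges the median over 26 genes was 1.03, with all 26 positive and 16 rising when adjusted over the list alone (camera adjusted p = 1.1e-12, and adjusted p = 0.26 with an estimated correlation). For microglia and macrophages it was 0.74 over 21 genes, with 15 rising when adjusted over the list alone (camera adjusted p = 6.9e-11, and adjusted p = 0.11 with an estimated correlation). For endothelial cells it was 0.45 over 24 genes, with none rising on either adjustment (camera adjusted p = 2.6e-06, and adjusted p = 0.28 with an estimated correlation). For interneurons and the ventral telencephalon it was 0.61 over 27 genes, with 7 rising when adjusted over the list alone (camera adjusted p = 2.3e-07, and adjusted p = 0.17 with an estimated correlation). For erythroid cells it was 0.30 over 12 genes, with 1 rising when adjusted over the list alone (camera adjusted p = 0.033, and adjusted p = 0.24 with an estimated correlation). With the block 3 genes of the pericyte and meninges list, 6 of the microglia list, 6 of the interneuron list and 2 of the erythroid list rose and 1 endothelial gene fell. Without both replicate 3 libraries the pericyte and meninges median was 0.60 and the endothelial median 0.28, and with a term for sex the erythroid median was 0.45. In fry the pericyte and meninges list (adjusted p = 0.062), the interneuron list (0.062), the endothelial list (0.10) and the erythroid list (0.13) did not pass. The microglia list did (fry adjusted p = 0.0091). The erythroid list passed in 18 of 27 alternatives. Its mean log2 level overlapped between the groups (3.44 to 4.09 in the control and 3.65 to 4.19 in the cKO). Interferon and innate immune genes were higher as a list (15 genes, none past the threshold on either adjustment, median 0.48, camera adjusted p = 0.029, and adjusted p = 0.28 with an estimated correlation), but not without both replicate 3 libraries (median 0.26, adjusted p = 0.12). They passed in 17 of 27 alternatives.

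4 classes of human malformation genes were examined. Of 29 lissencephaly genes, the reelin pathway members Dab1 (17.5 ± 2.75 against 39.7 ± 5.64 FPKM, adjusted p = 0.026) and Lrp8 (19.2 ± 3.96 against 40.8 ± 0.411 FPKM, adjusted p = 0.031) fell, also when adjusted over the list alone, and none rose. The list median was -0.33 (camera adjusted p = 1.0e-04, and adjusted p = 0.28 with an estimated correlation), -0.22 without both replicate 3 libraries and -0.50 with a term for sex. Of 15 periventricular heterotopia genes, the ubiquitin ligase Nedd4l fell 2.05-fold (3 fell and 1 rose when adjusted over the list alone; median -0.33, camera adjusted p = 0.044, and adjusted p = 0.34 with an estimated correlation), and it overlaps A330084C13Rik, which also fell. With the block 2 genes of this list fell. It passed in 13 of 27 alternatives, and neither with a term for sex (median -0.074, adjusted p = 0.29) nor without both replicate 3 libraries (median -0.17, adjusted p = 0.095). Of 38 microcephaly genes none passed on either adjustment (median -0.17, camera adjusted p = 0.049, and adjusted p = 0.60 with an estimated correlation), 2 fell with the block, and the list did not pass with a term for sex (median 0.10, adjusted p = 0.54). It passed in 15 of 27 alternatives. Of 31 cobblestone cortex genes, only the adhesion receptor Adgrg1 (GPR56) passed, falling 1.75-fold, while 23 genes had a positive log2 fold change (median 0.18, camera adjusted p = 0.011, and adjusted p = 0.36 with an estimated correlation). The cobblestone median was 0.077 without both replicate 3 libraries and 0.12 with a term for sex. Among 26 pial basement membrane genes, the laminin chain Lamb2 rose 2.79-fold (2 rose when adjusted over the list alone; median 0.45, camera adjusted p = 2.1e-07, and adjusted p = 0.28 with an estimated correlation), the median was 0.28 without both replicate 3 libraries, and Lama1 measured 5.39 ± 0.714 against 5.15 ± 1.37 FPKM (adjusted p = 0.89). In 39 genes of apical junctions and polarity, N-cadherin (Cdh2) fell 1.81-fold (adjusted p = 0.0493) and the apical polarity gene Crb1 rose 6.32-fold (4 rose and 1 fell when adjusted over the list alone). That list did not pass (median 0.06, camera adjusted p = 0.15), and with the block 6 of its genes rose and 2 fell.

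Of 27 BAF subunit genes only Bcl7a fell (23.1 ± 0.517 against 39.8 ± 1.86 FPKM, adjusted p = 0.028), also when adjusted over the list alone, and its exons overlap Gm15860 (median -0.14, camera adjusted p = 0.034, and adjusted p = 0.34 with an estimated correlation). With the block 2 of them fell. The list passed in 15 of 27 alternatives, not without both replicate 3 libraries (median -0.058, adjusted p = 0.19), and had a median of -0.26 with a term for sex. The paralogous ATPase Smarca2 measured 10.8 ± 1.56 against 16.3 ± 3.23 FPKM (adjusted p = 0.20), with the antisense gene 4931403E22Rik overlapping it, and Arid1a 33.5 ± 7.21 against 36.2 ± 2.71 FPKM (adjusted p = 0.79). Transcription factors made up 16.4% of the higher genes (22 of 134) and 12.4% of the lower genes (26 of 210), against 6.26% of the genes tested (two-sided Fisher's exact test, adjusted p = 5.7e-05 and 8.1e-04). Fisher's test treats genes as independent draws, so these p-values do not measure the spread between libraries. Of 65 tested homeobox factors 7 rose and none fell, among them Nkx2-4, Uncx, Lmx1a, Irx3 and Irx5.

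Lists chosen as checks on RNA quality did not pass: replication-dependent histones (adjusted p = 0.74), cytoplasmic ribosomal proteins (adjusted p = 0.12), mitochondrially encoded genes (adjusted p = 0.20), glycolysis and hypoxia (adjusted p = 0.77) and immediate early and stress genes (adjusted p = 0.25). No gene in them passed over all genes in limma, although 1 glycolysis gene rose and 1 fell with the block, and 1 histone gene rose when adjusted over its list alone. The ribosomal and mitochondrial lists passed as lower with the block (adjusted p = 0.044 and 0.025, and adjusted p = 0.79 and 0.61 with the block and an estimated correlation). Without both replicate 3 libraries the ribosomal list also passed (median -0.24, adjusted p = 6.5e-05). In the main test the glycolysis list had a median of -0.04 with a test direction upwards. The sex-linked list (5 genes) passed as higher (camera adjusted p = 0.034, and adjusted p = 0.29 with an estimated correlation) but not with the block (adjusted p = 0.055) or a term for sex (adjusted p = 0.40). It passed in 13 of 26 alternatives. Adjusted over the list alone, 4 of its genes rose and 1 fell. No Hox gene and 3 germline genes reached the expression filter, too few for a test, and the 3 germline genes did not pass. Across genes, which are not independent replicates, the log2 fold change had a Spearman correlation of -0.10 with gene length.

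On the mean log2 level per library, 21 of 36 lists reached the smallest p of 0.1 that an exact permutation test of 3 against 3 can give. Called lists that did not reach it in this exact permutation test were the erythroid list (p = 0.5), G2 and M phase and microcephaly (p = 0.4), and the Notch, synapse and sex-linked lists (p = 0.2). All 26 list calls of camera (16 higher and 10 lower) rested on the preset correlation, since none of 36 lists passed with an estimated correlation, and neither did any of the 28 called with the block, while fry, which does not compare a list with other genes, called 11. The count of 344 genes fell to 0 without control replicate 1 (1914 genes at an unadjusted p under 0.05), 58 without control replicate 2, 172 without control replicate 3, 90 without cKO replicate 1 and 21 without cKO replicate 2, and rose to 1863 without both replicate 3 libraries. In replicates 1 and 2 both controls were female and both cKO libraries male by Xist and Ddx3y, so group and sex coincided. Of these 1863 genes, called in replicates 1 and 2 alone, 1685 (90.4%) had the same direction in the pair of replicate 3 libraries. The log2 fold changes of the 2 subsets had a Pearson correlation of 0.52 across 15915 genes. With a term for sex, which leaves control replicate 3 as the only male control, 204 genes changed, and these held 107 of the 344.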

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

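The tests added after the result was seen left out both replicate 3 libraries, used voom, dropped the scaling factor, added a term for sex, kept autosomes only, or corrected for GC content and length; the others were planned. All 344 changed genes kept their direction in every setting in which they were tested, and of 66 named genes past the threshold none reversed. The control and cKO values of all 344 were apart. Settings that only left out, weighted or paired libraries, or added the term for sex, could therefore not reverse them. Their direction was tested only by settings that rescaled the values or corrected them for GC content and length. Of the 66 named genes, 26 stayed past the threshold in every setting apart from leaving out a library. The counts of changed genes stayed within 1.5 times of 344 with pseudocounts of 0.1 and 1 (323 and 350), a mean FPKM of at least 1 (340), the TPM scale (402), quantile normalisation (354), no trend (373), robust moderation (330), protein-coding genes only (509), voom (476), no scaling factor (436) and autosomes only (349). Median-ratio factors were equal for every library and so tested nothing. The cause of the changes below was not tested, apart from fewer libraries where some were left out and more genes tested without a filter. The term for sex also acted as a loss of controls, since it compared the cKO libraries with control replicate 3 alone. Depth limits calls of low genes, since 3 reads were the floor in libraries of 16900332 to 18689748 reads.

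With the replicate block, which pairs the libraries by number, 886 genes changed, 445 of them at least 2-fold, and 134 distinct list members passed against 63. The pairing of numbers 1 and 2 within the block was not supported by the check of the deviations. Mki67 and the lists of S phase, oligodendrocytes and astrocytes, ribosomal proteins and mitochondrial genes gained a call, and the synapse and sex-linked lists lost theirs. The block changed no other call of a named gene or list. The block with voom gave 1865 genes (851 at least 2-fold), 221 list members and a Smarca4 log2 fold change of -1.18 past the threshold, and the block with the GC and length correction gave 1263 genes (486), 170 list members and a Spearman correlation of the log2 fold change with gene length of 0.0166.

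With no filter on low values 184 genes changed (151 at least 2-fold) with 32 list members. With limma arrayWeights 5181 genes changed (801), with 426 list members, a log2 fold change of the targeted gene, Smarca4, of -1.34 past the threshold and a length correlation of -0.0042; Arid1a turned to 0.14 and Pax6 to -0.034. The Arid1a log2 fold change also turned to 0.032 on the TPM scale, 0.067 with quantile normalisation and 0.065 without the scaling factor. Without both replicate 3 libraries 1863 genes changed (480), with 239 list members and a length correlation of -0.0145; Arid1a turned to 0.12, Pax6 to -0.042 and Lama1 to -0.16. With the GC and length correction 1199 genes changed (478), with 147 list members, a length correlation of 0.0166 and a Smarca4 log2 fold change of -1.14 past the threshold, as was -1.18 with voom. With a term for sex 204 genes changed, with 39 list members, a length correlation of 0.0109 and Mki67 at 0.30.

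Among gene list tests, 26 lists passed with the preset correlation, 0 with an estimated correlation in camera (2653 single genes had an unadjusted p under 0.05 in limma) and 11 with fry. The direction of a list's test turned in these cases, given as medians. With a term for sex they were S phase 0.23, G2 and M phase 0.23, microcephaly 0.10, mitochondrial genes 0.29, histones 0.019, oligodendrocytes and astrocytes 0.029, apical radial glia -0.13 and glycolysis -0.27. Without both replicate 3 libraries they were the synapse list -0.0037, glycolysis -0.020 and immediate early genes 0.035. Glycolysis also turned with no filter (-0.0087) and in fry (-0.037), histones with a mean FPKM of at least 1 (0.049), and apical radial glia (0.042) and ribosomal proteins (0.081) with quantile normalisation.

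Leaving out each library in turn gave 0 to 303 changed genes, 0 to 236 of them at least 2-fold, 0 to 57 list members, 17 to 27 lists and length correlations of -0.153 to 0.0386. The count was 0 in limma without control replicate 1, where 1914 genes had an unadjusted p under 0.05, and 58, 172, 90 and 21 without control replicates 2 and 3 and cKO replicates 1 and 2. Log2 fold changes ran from -0.25 to 0.058 for Arid1a, -0.15 to 0.15 for Pax6 and -0.086 to 0.26 for Lama1. List medians ran from -0.14 to 0.088 for glycolysis, -0.40 to -0.12 for histones, -0.15 to 0.23 for immediate early genes and -0.57 to 0.038 for mitochondrial genes.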

Other observations

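All tests in this part were chosen after the result was seen, apart from the share of GC content and length and the test of developmental age in the replicate 3 libraries. The genes named here and not in the report were chosen after their values were seen. The zinc finger factor Zic2 rose from 17.4 ± 3.44 to 53.9 ± 12.3 FPKM (limma adjusted p = 0.0198). The serine synthesis enzyme Psat1 rose 2.80-fold (adjusted p = 0.0185) and the metallothionein Mt1 2.93-fold (adjusted p = 0.0080).

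A list of genes of motile cilia was written after several of them were seen among the higher genes. Of 56 tested, 11 rose and none fell, Tekt1 (3.75-fold) and Dynlrb2 (6.37-fold) among them. The 45 members not past the threshold had a median log2 fold change of 0.961, with 43 positive (camera p = 1.5e-19, p = 0.059 with an estimated correlation, and p = 0.16 with the block as well). By the bound set, this counted as a rise of the group. However, 14 of the 56 genes stood at 1 FPKM or more in every control, so members could reach the expression filter through their cKO values. This favoured positive fold changes, and the test cannot decide on a rise of the group. The list mean ranked the 6 libraries in the same order as the mean of 8 choroid plexus epithelium genes. A second list held imprinted genes, after Dio3, Magel2 (5.53-fold), Peg10 (4.32-fold) and Asb4 (4.03-fold) were seen among the higher genes. The 41 other tested members had a median of 0.0541, with 26 positive and quartiles of -0.11 and 0.57, so a rise of the group stayed undecided, although camera gave p = 0.0033 (p = 0.025 with an estimated correlation, and p = 0.070 with the block as well). With the block 3 of these 41 rose. The condition on the quartiles was added after these values were seen, and without it the list would have counted as higher.

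Lists of the hem and choroid plexus and of the diencephalon were higher in the cKO and those of cortical neurons lower. Choroid plexus epithelium (8 genes, 4 at 1 FPKM or more in every control) was argued against as the source of the hem ligands. Its most abundant gene, Ttr, stood at 309 ± 251 FPKM in the control against 1539 ± 1176 FPKM in the cKO. The epithelium mean varied by 1.74 log2 units among the controls. The mean of the 7 ligands rose by 1.29, 3.94 times the range of that mean among the controls (6.69 times without both replicate 3 libraries). The rise was not shared by Rspo3, 1 of the 7 ligands (log2 fold change 0.048, limma adjusted p = 0.95). Dilution of cortical RNA was argued against as the whole cause of the lower cortical genes, which moved unevenly, with log2 fold changes of -0.44 for Emx1 and -1.85 for Neurod6 (Cochran's Q over degrees of freedom 13.35 over 6 genes, and 76.7 without both replicate 3 libraries). Whether diencephalic tissue was carried over in dissection stayed open, since the 88.9% of list members higher in every cKO library than in every control restates the pattern on 9 of 24 genes, of which 1 stood at 1 FPKM or more in every control. Expression of such genes in cortical cells lacking Brg1 stays open as an untested biological hypothesis.

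The replicate 3 libraries of both groups shared a deviation from replicates 1 and 2 (Pearson 0.526 across genes). Sex was argued against as its cause, since Xist was at most 0.0151 FPKM in all 3 cKO libraries. By the bound set beforehand a different age would be argued against. The upper-layer minus intermediate progenitor mean shifted by -0.537 in the cKO and by 0.264 in the control. Both of these lists were themselves lower in the cKO, so this mean need not measure age there, and the test cannot decide. The means of G2 and M phase shifted by -0.437 and -0.703 in the cKO and the control, and those of S phase by -0.245 and -0.548. A different age and a shared difference in cycling cells therefore stay open. A bias by GC content and length could account for part of it, with 26.2% of the variance of the deviation in the control and 42.9% in the cKO, against 0.836% and 0.708% between replicates 1 and 2. The bound of 30% in both groups set beforehand was missed in the control alone, so this stayed undecided, and as the whole cause it was argued against, since the SD left after its removal was at least 1.5 times that of replicates 1 and 2.

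Marker lists of several non-neuronal cell types were higher in the cKO. They did not rise alike, since the pericyte and meninges list rose by 0.552 log2 units more than the endothelial list. Without both replicate 3 libraries it rose by 0.333 more (25 of 26 and 21 of 24 of their genes stood at 1 FPKM or more in every control). Among the controls this difference was 0.558, 0.551 and 0.0141 in replicates 1 to 3. By the bound set, a lower share of neural cells would be argued against as the whole cause. That bound assumes that the other cell types keep their ratios to each other, which was not measured, so the test cannot decide. Meningeal tissue carried over is a candidate source, since 4 markers of border macrophages rose by 0.769 log2 units more than 7 of parenchymal microglia, and by 0.460 more without both replicate 3 libraries. The most abundant of the former, Pf4, stood at 20.04 ± 10.9 against 7.68 ± 0.733 FPKM in the cKO against the control, and Cx3cr1, among the latter, at 5.06 ± 0.210 against 3.43 ± 0.476 FPKM. An earlier test on the whole microglia list, which rose by 0.727, had argued against meningeal tissue and was replaced because that list holds macrophages, and a change of these cells in the cKO stays open.

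Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many genes as the real split, namely the real split itself, with 344 genes, and the highest other gave 2. The splits are too few for a share under 0.05. The other 3 splits that part all 3 numbered pairs gave 0 genes each in limma, where the real split had 2653 genes at an unadjusted p under 0.05.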
